A study of Mus musculus with 10 samples.

How the data were processed

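RNA was measured in CD8 T cells sorted from subcutaneous MC38 tumours of C57BL/6 mice. MC38 is a mouse colon carcinoma line, implanted at 500000 cells per mouse. The mice received either vehicle or JHU083 from day 14 to day 18 after implantation, and tumours were harvested on day 18. JHU083 is a prodrug of 6-diazo-5-oxo-L-norleucine, an antagonist of glutamine-using enzymes. The labels give its dose as 0.3 mg per kg per day. The sort kept cells positive for CD45, TCR beta, CD44 and CD8 and negative for CD11b, CD11c and B220. Poly(A) RNA was made into libraries with a NEBNext Ultra kit, which does not mark strand, so reads of a gene and of an overlapping antisense gene were not separated. The labels place 5 libraries in the vehicle group (replicates 1, 2, 3, 4 and 6) and 5 in the JHU083 group (replicates 1, 2, 4, 5 and 6). They do not say in words that each library is a different mouse, so p-values measure the spread between these libraries.

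Per the submitters' processing notes, the reads were handled with bcl2fastq 2.17.1.14, FastQC 0.11.2 and TopHat2 2.1.1, and the genome build was GRCm38. The counter, its treatment of reads that map to several places and the gene annotation are not given in the sources used here. The authors deposited, per the file headers, raw estimated counts per gene locus for each library, not normalized. Of the values above 0, 12.4% were not whole numbers, with a largest distance from a whole number of 0.382, so expected counts were rounded to whole numbers before the count test. The table has 50538 rows. In 642 of them several gene symbols share one locus, and list members found only in such rows were left out. Another 140 rows repeat a symbol, over 63 symbols, and a list member with several rows was represented by the row with the most counts. Every row carries a gene name. Library totals ranged from 19579872 to 40522394 counts.

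The authors' deposited table of their own comparison gives, per the file headers, an FPKM value per group, a log2 fold change, a p-value and a q-value per gene, with a test status. Its log2 fold change was found to be vehicle over JHU083 and was turned around here. The deposited sheet that describes the columns states the opposite order, and the group FPKM values decided the direction. The status HIDATA marks loci that the quantifier skipped as too deep and FAIL marks loci where its computation failed, and this status was used to recognise rows whose 0 is no measurement. The authors' deposited gene set enrichment sheet was read for its set members and its enrichment score. The other sheets were not used here.

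The main comparison was made with edgeR 4.0.16 (R 4.3.3): rows were filtered with filterByExpr, libraries scaled with TMM (factors from 0.964 to 1.03), and each row tested with the two-sided quasi-likelihood F test of glmQLFit and glmQLFTest with the group as the only term. The Benjamini-Hochberg adjusted p was taken over all 15307 rows tested, with a threshold of 0.05. CPM values are TMM-scaled. The standard error of a log2 fold change was its size divided by the square root of F. On simulated counts with the real means, library sizes and dispersions, run on 15045 genes for JHU083 against vehicle, the test recovered 89.4% of genes changed 4-fold, 64.2% of those changed 2-fold and 25.4% of those changed 1.5-fold. Of its 128 calls, 9 were false, or 7%. Recovery was not split by abundance, so the simulation does not measure precision at low counts. These counts have no molecular identifiers. The simulated genes were drawn independently, with 66 or 67 changed at each fold, where 51.4% of rows were called in the real data.

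Before the data were examined, 26 gene lists were fixed, 16 of biological processes and 10 of cell type markers. Each was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and the adjusted p was taken over the lists with at least 2 tested members. The erythroid list had 1 tested member and has no such test. In a simulation with 26 lists of 20 genes on 15025 genes, the list shifted 2-fold was called and 0 others were. Its genes were drawn independently, while the estimated correlation of the real lists reached 0.72. It therefore cannot show how camera behaves on correlated lists. Camera was repeated with an estimated correlation, and fry, which asks whether the members of a list move one way on balance, was run as an alternative. For each marker list the CPM of its members was also summed per library, and the group means were compared with a two-sided exact permutation test over all assignments of the libraries, for which 0.00794 is the smallest p possible.

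The rule for named genes was fixed at the same time. Its first part takes the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 10 CPM and no overlap between groups, leaving out receptor and immunoglobulin segments and predicted models. Its second part takes up to 3 members with the smallest p in each process list. The third is 16 genes fixed by name, and the fourth is the most abundant member of each marker list that is in no process list. Some genes this rule takes are not reported here. A list of 34 adherent-cell genes, which blood cells mostly lack, was written after the first fit had shown such genes high in vehicle libraries. Its index in a library is the median over the tested members of CPM divided by the gene's mean. The CD8 identity ratio is the median over the tested CD8 T identity genes of CPM divided by the JHU083 mean.

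Alternatives planned before the data were examined were DESeq2's median-of-ratios factors, upper-quartile factors and total counts as scaling, no low-count filter, a filter of 5 CPM in 5 libraries, DESeq2 1.42.0, limma-voom with quality weights, robust dispersion, leaving out each library, the replicate number as a block, and a surrogate variable from sva 3.50.0. Chosen after seeing the data were the adherent-cell index as a covariate, a comparison with vehicle replicates 3 and 6 only, scaling to the CD8 T identity genes, and removal of HIDATA and FAIL rows. For 4 lists the mean log2 CPM of the members per library was also fitted on group and index by least squares, a test likewise chosen after seeing the data. Between replicates of a group, squared count differences were at least 14.8 times the counting variance in each of the 20 pairs, so no library looked like a second copy of another. Gene coordinates are from GENCODE vM21, which uses the build named in the processing notes.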

Results

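Gene expression was measured by RNA-seq in 10 libraries of sorted, antigen-experienced CD8 T cells from MC38 tumours, 5 from mice given vehicle and 5 from mice given JHU083. The comparison asked how treatment with a glutamine antagonist prodrug changed the transcriptome of CD8 T cells in the tumour. Total counts were 40522394, 26225234, 24395913, 22385857 and 23076476 in vehicle replicates 1, 2, 3, 4 and 6, and 22825044, 19917505, 19858355, 19579872 and 21559122 in JHU083 replicates 1, 2, 4, 5 and 6.

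Expression differed widely between the groups. Genes of glycolysis, the hypoxia response, sterol and fatty acid synthesis, the amino acid response, nucleotide synthesis and ribosome biogenesis were lower in JHU083 libraries, though none of these lists passed with an estimated correlation (adjusted p from 0.365 to 0.633). The cholesterol exporters Abca1 and Abcg1, the transcription factors Foxo1, Tcf7 and Satb1 and the Nr4a receptors were higher, and of these Foxo1, Tcf7, Satb1, Nr4a1 and Nr4a3 did not pass with a surrogate variable. The vehicle libraries also held transcripts of adherent, non-lymphoid cells at levels far above those of the JHU083 libraries. Of 15307 rows tested with edgeR, 3671 were higher and 4192 lower in JHU083, which is 51.4% of the rows, and 934 and 2208 of them changed more than 2-fold. The groups did not overlap in 5286 rows, or 34.5%, where chance gives 0.79%. The first principal component held 72.3% of the variance. Vehicle replicates 2, 4, 1, 6 and 3 lay on it at -124.2, -94.5, -88.2, -20.9 and -15.8, and the JHU083 libraries between 52.5 and 85.5. This is also the order of the libraries by the adherent-cell index, described next, so the component does not separate treatment from that index. When libraries were scaled to their CD8 T identity genes instead of by TMM, 448 rows were higher and 7243 lower, so 5.8% of the calls were rises against 46.7%, and the median log2 fold change of all rows moved from 0.04 to -0.65. With the adherent-cell index as a covariate the counts were 882 and 1527. Against vehicle replicates 3 and 6 only, which had the lowest index of the vehicle group, they were 1481 and 1964. With a surrogate variable they were 90 and 263. How far that variable follows the group or the index was not measured, so a call lost with it does not show that a change is absent. The scaling to CD8 genes, the covariate and the smaller vehicle group were chosen after seeing the data.

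Transcripts of other cell types were measured in each library with marker lists. The adherent-cell index, built on genes such as the receptor tyrosine kinases Axl and Egfr and the caveolar gene Cav1, was 2.01, 3.28, 0.626, 2.28 and 0.752 in vehicle replicates 1, 2, 3, 4 and 6, and between 0.0906 and 0.264 in the JHU083 libraries (exact permutation test, two-sided, p = 0.00794, the smallest possible). Of its 31 tested members, 30 fell and 1, Tjp1, rose, with a median log2 fold change of -3.11. The list was chosen after such genes had been seen to differ, so this count is not independent evidence of its direction. Over the same vehicle libraries the CD8 identity ratio was 0.603, 0.383, 0.813, 0.633 and 0.873, and it was 0.849 to 1.07 in the JHU083 libraries (exact permutation test, p = 0.0159).

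**Figure D1:**
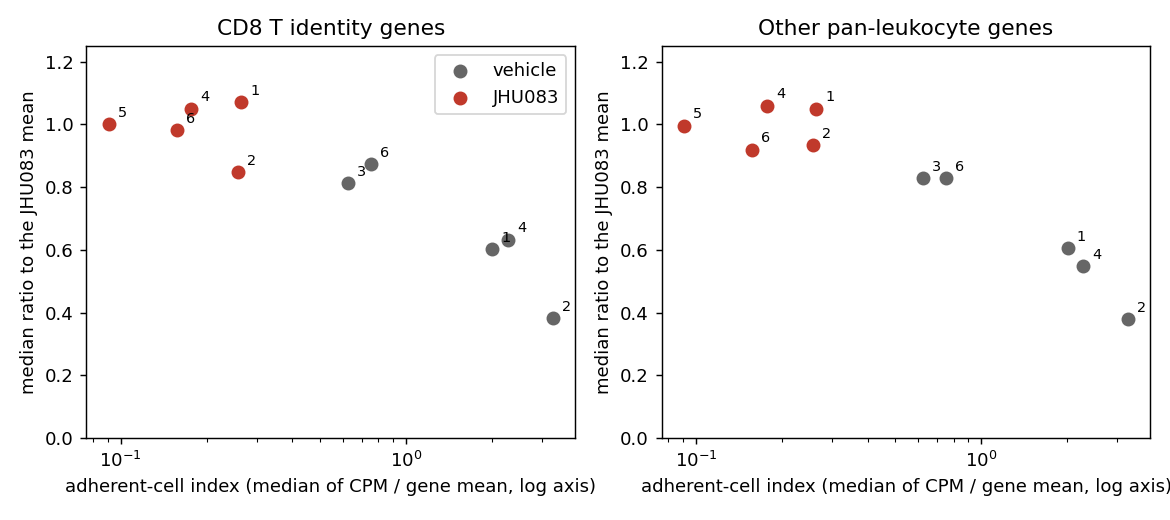
Median ratio of CD8 T identity genes (left) and of other pan-leukocyte genes (right) to their JHU083 mean, against the adherent-cell index on a log axis, with 1 point per library and its replicate number. The vehicle library with the highest index, 3.28, had the lowest CD8 identity ratio, 0.383.

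Among the fixed marker lists, the 20 genes of CD8 T identity were higher in JHU083, with 12 that rose, 0 that fell and 8 that did not pass (camera adjusted p = 0.00211; adjusted p = 0.68 with an estimated correlation). Adjusted over the list alone the counts were again 12 and 0. Cd8a, which encodes a chain of the CD8 coreceptor, was at 1263 ± 386 CPM in vehicle and 1794 ± 183 CPM in JHU083 (SD, n = 5 each), a log2 fold change of 0.51 ± 0.20 (SE) with an adjusted p of 0.0498. This call ended without vehicle replicate 1, 2 or 4 (adjusted p of 0.113, 0.0737 and 0.104) and without JHU083 replicate 1, 4, 5 or 6 (0.0808, 0.099, 0.0785 and 0.098). It also ended with upper-quartile or total-count scaling (0.0537 and 0.07), no filter or a stricter one (0.0683 and 0.0524), robust dispersion (0.0509) and against vehicle replicates 3 and 6 only (0.13, adjusted p = 0.54), and the sign turned with a surrogate variable (-0.21, adjusted p = 0.7) and with the index as a covariate (-0.10, adjusted p = 0.66). The mean of the list was 0 with that covariate and -0.05 with a surrogate variable, against 0.53. The list did not pass in either fit (adjusted p of 0.973 and 0.628). Of 15 fibroblast and endothelial markers, 11 fell and 1 rose (adjusted p = 0.00471; adjusted p = 0.68 with an estimated correlation), and adjusted over the list alone the counts were the same. The list did not pass with the index as a covariate (adjusted p = 0.199) or with a surrogate variable (adjusted p = 0.654). Fn1, which encodes fibronectin, was at 2714 ± 1751 CPM in vehicle and 299.5 ± 164 CPM in JHU083, a log2 fold change of -3.18 that was -1.31 with the index as a covariate (adjusted p = 0.0409) and -0.75 with a surrogate variable (adjusted p = 0.472). Of 8 dendritic cell markers, 6 fell and 1 rose (adjusted p = 0.0453; adjusted p = 0.367 with an estimated correlation), among them Cd74, the invariant chain of MHC class II, at 111.1 ± 106 CPM against 20.9 ± 9.16 CPM. Adjusted over the list alone the counts were the same. Without vehicle replicate 2 the log2 fold change of Cd74 was -1.62 against -2.41, and its call ended with the index as a covariate (-0.87, adjusted p = 0.194) and with a surrogate variable (-0.90, adjusted p = 0.617). The list did not pass there either (adjusted p of 0.142 and 0.0691), nor with total-count scaling (0.0654), a stricter filter (0.309) or limma-voom (0.154). The list call was lost without vehicle replicate 1, 2, 3, 4 or 6 (adjusted p of 0.0685, 0.0569, 0.0606, 0.111 and 0.155) and without JHU083 replicate 1 or 4 (0.13 and 0.149). The macrophage list (6 fell of 10), neutrophil list (2 fell and 1 rose of 4), B and plasma cell list (2 fell of 8), tumour epithelial list (2 fell of 6), CD4 and regulatory T cell list (1 fell of 10) and NK and gamma-delta T cell list (1 rose and 1 fell of 10) did not pass, with adjusted p values of 0.194, 0.752, 0.692, 0.752, 0.917 and 0.886. Adjusted over the list alone, the counts of these lists were the same. Without a low-count filter, which had removed C1qa, C1qb and C1qc, the macrophage list was lower (mean -3.62 against -2.07, adjusted p = 0.0038). With the filter, leaving out vehicle replicate 2 moved that mean to -0.74. C1qa was at 48.5 CPM in vehicle replicate 2 and at 4.79 CPM or less in each other library. The tumour epithelial list had a median log2 fold change of 0.27 and a mean of -0.86, which was -0.26 without vehicle replicate 4, 0.26 against vehicle replicates 3 and 6 only, and -0.66 with a surrogate variable, where the list was lower in JHU083 (adjusted p = 0.0392), as it was in the self-contained test fry (adjusted p = 0.00695). The CD4 and regulatory T cell list was lower with the index as a covariate and with a surrogate variable (adjusted p of 0.0292 and 0.0231), and the NK list had a mean of -0.08 while camera's direction was up. In the erythroid list 1 member, Alas2, was tested and rose from 0.413 ± 0.175 to 0.799 ± 0.202 CPM (adjusted p = 0.0484), a call that ended in 8 of the fits that left out a library, with adjusted p values from 0.0535 to 0.125. The Alas2 call also ended with DESeq2 size factors (0.0511), total-count scaling (0.0625), no filter (0.175), robust dispersion (0.0507), DESeq2 (0.0584), limma-voom (0.0631), a surrogate variable (0.682), the index as a covariate (0.483) and vehicle replicates 3 and 6 only (0.303). Summed CPM differed between groups for 9 of the 10 marker lists (exact permutation tests, adjusted over the lists), the exception being the CD4 and regulatory T cell list with an adjusted p of 0.563. That count was 0 without JHU083 replicate 2, 4 or 6 and 2 without JHU083 replicate 5, with the lost calls at adjusted p values of 0.0567 to 0.0617. The fibroblast and endothelial sum was 7261 ± 4680 CPM in vehicle and 1133 ± 496 CPM in JHU083.

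The 6 largest falls that met the naming rule included Wnt7b (a secreted Wnt ligand), Met (the hepatocyte growth factor receptor), Aldh1l2 (a mitochondrial folate enzyme), Hmga2 (a chromatin protein of fetal and tumour cells) and Fads2 (a fatty acid desaturase). In GRCm38 they lie on chromosome 15 from 85535437 to 85582473, chromosome 6 from 17463800 to 17573980, chromosome 10 from 83487450 to 83534140, chromosome 10 from 120361275 to 120476469 and chromosome 19 from 10062765 to 10101746. Met was at 38.6 ± 25.8 CPM in vehicle and 0.533 ± 0.195 CPM in JHU083, a log2 fold change of -6.17 ± 0.59 (SE, adjusted p = 0.00015). Wnt7b changed by -6.84 ± 0.72, Aldh1l2 by -6.03 ± 0.62, Hmga2 by -5.86 ± 0.49 and Fads2 by -5.73 ± 0.62 on the log2 scale. Against vehicle replicates 3 and 6 only Met, Wnt7b, Aldh1l2, Hmga2 and Fads2 still passed at -4.55, -5.09, -4.39, -4.53 and -4.29, and with the index as a covariate at -4.18, -4.70, -3.99, -4.20 and -3.89. Within the vehicle group Met followed the adherent-cell index, at 43.3, 71.1, 12.6, 53.5 and 12.6 CPM in replicates 1, 2, 3, 4 and 6. The largest rises included Abca1 and Abcg1, exporters of cholesterol, at chromosome 4 from 53030787 to 53159895 and chromosome 17 from 31057675 to 31117988. Abca1 rose from 3.72 ± 4.64 to 90.7 ± 31.4 CPM, a log2 fold change of 4.61 ± 0.68 (adjusted p = 0.000411), and Abcg1 from 10.2 ± 3.97 to 126.2 ± 15.9 CPM, a log2 fold change of 3.64 ± 0.24 (adjusted p = 1.9e-05). Qrfp, which encodes a neuropeptide precursor, and the hair keratin gene Krt83 rose by 2.48 ± 0.28 and 2.34 ± 0.28 on the log2 scale, and with a surrogate variable Krt83 did not pass (1.64, adjusted p = 0.0566). Qrfp and Krt83 were both at 1.68 with the index as a covariate. Against vehicle replicates 3 and 6 only, Abca1 and Abcg1 rose by 6.34 and 3.18, and without vehicle replicate 2 Abca1 rose by 5.77. They rose by 7.45 and 3.09 with the covariate.

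The other 3 genes the rule took were listed at 0 in a whole group. Hspa1a and Hspa1b, near-identical genes of the inducible heat shock protein 70, were listed at 0 in every vehicle library. Their counts in JHU083 replicates 1, 2, 4, 5 and 6 were 29114, 22809, 12071, 36379 and 28270 for Hspa1a and 42115, 36546, 19959, 48696 and 40350 for Hspa1b. The mitochondrial row mt-Nd1,mt-Nd2 was listed at 0 in every JHU083 library and at 195884, 127350, 156733, 134870 and 177623 in vehicle replicates 1, 2, 3, 4 and 6. The authors' deposited table marks all 3 rows HIDATA, so no fold is given for them.

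Genes of glycolysis fell together. Of 23 members, 20 fell, 0 rose and 3 did not pass (camera adjusted p = 5.35e-09; adjusted p = 0.365 with an estimated correlation), with the same counts adjusted over the list alone. Pgk1 (phosphoglycerate kinase) fell from 909 ± 156 to 234 ± 68.5 CPM, a log2 fold change of -1.96 ± 0.19 (adjusted p = 0.00015), Eno1 (enolase) from 1331 ± 149 to 440.4 ± 120 CPM and Pfkl (phosphofructokinase) from 191 ± 33.9 to 61.96 ± 15.6 CPM. Slc2a1, the glucose transporter GLUT1, fell less, from 176 ± 26.5 to 124 ± 5.42 CPM, and with the index as a covariate its adjusted p was 0.17, and 0.76 with a surrogate variable. Pgk1, Eno1 and Gapdh have processed copies in the genome that could share reads, and the authors' table marks Gapdh FAIL. In the hypoxia list 18 of 24 members fell and 3 rose (adjusted p = 1.62e-05; adjusted p = 0.367 with an estimated correlation), or 19 and 3 adjusted over the list alone. Mif, a cytokine gene induced by hypoxia, fell from 206.5 ± 51.1 to 40.6 ± 16.8 CPM, Bnip3, a mitophagy receptor, from 95.4 ± 42.0 to 12.6 ± 4.56 CPM, and Ankrd37 from 15.3 ± 2.62 to 5.78 ± 0.579 CPM. With the index as a covariate, 18 of the 20 glycolysis genes and 12 of the 18 hypoxia genes that fell still passed in the same direction, and against vehicle replicates 3 and 6 only 19 and 17 did. The covariate moved the list means from -1.21 to -1.01 and from -1.39 to -0.82, and Bnip3 from -2.92 to -1.85.

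**Figure D2:**
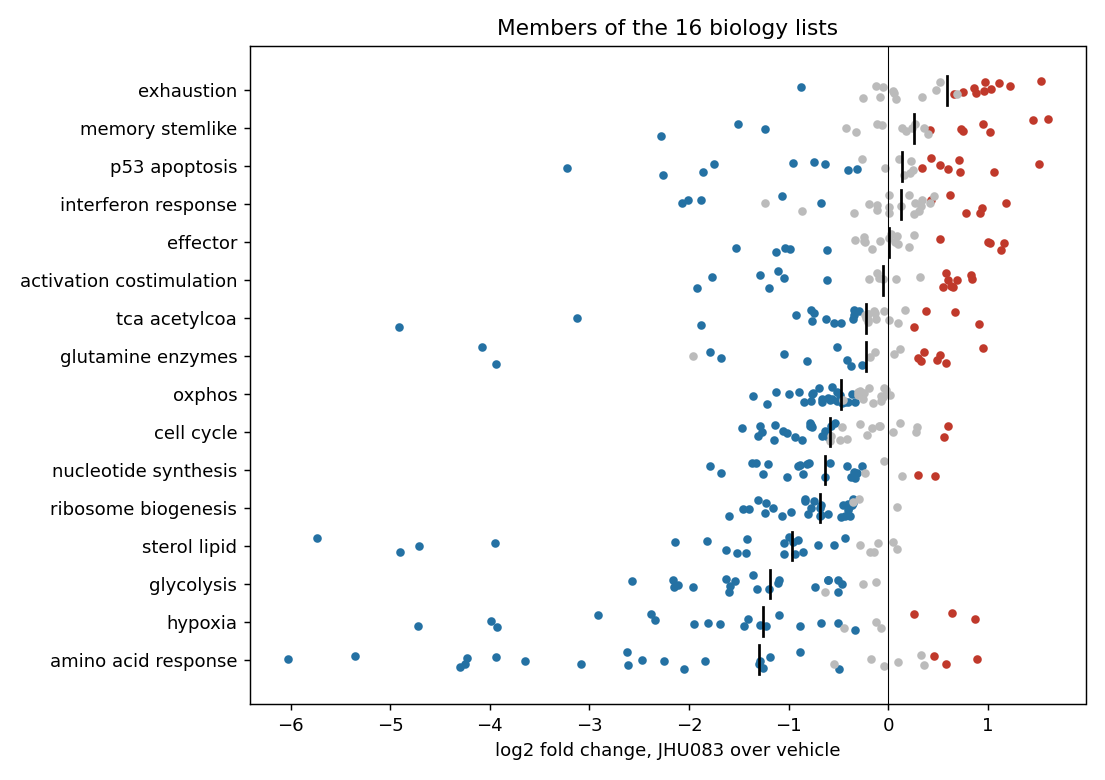
log2 fold change, JHU083 over vehicle, of each tested member of the 16 process lists, with 1 point per gene, red for rose, blue for fell, grey for did not pass, and a black bar at the list median. The medians run from -1.3 for the amino acid response to 0.59 for exhaustion.

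Lipid genes also fell. In the sterol and fatty acid list 20 of 26 members fell and 0 rose (camera adjusted p = 1.01e-08; adjusted p = 0.365 with an estimated correlation), with the same counts adjusted over the list alone. Idi1, an enzyme of cholesterol synthesis, fell from 48.8 ± 4.98 to 18.1 ± 2.08 CPM, a log2 fold change of -1.43 ± 0.11 (adjusted p = 4.97e-05), and of -1.41 against vehicle replicates 3 and 6 only. With the index as a covariate 16 of the 20 still passed, and the list mean was -0.93 against -1.47.

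Genes that use or respond to amino acids moved in both directions. Among 22 glutamine enzymes and transporters, 10 fell and 7 rose, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.343), but was lower with a surrogate variable (adjusted p = 0.0381) and in the self-contained test fry (0.000202). Asns (asparagine synthetase) fell from 125.8 ± 73.6 to 8.20 ± 1.90 CPM, Gpt2 (a mitochondrial alanine transaminase) from 51.7 ± 31.9 to 3.04 ± 1.17 CPM, and Pfas, a glutamine-dependent enzyme of purine synthesis, from 59.95 ± 13.0 to 18.8 ± 3.35 CPM. The log2 fold changes of Asns and Gpt2, -3.94 and -4.08, were -2.29 and -2.24 with the index as a covariate and -2.58 and -2.57 against vehicle replicates 3 and 6 only. In the amino acid response list 20 of 29 members fell and 3 rose (adjusted p = 3.02e-05; adjusted p = 0.633 with an estimated correlation), or 20 and 4 adjusted over the list alone. Psat1, an enzyme of serine synthesis, fell from 280.0 ± 132 to 45.7 ± 5.57 CPM, a log2 fold change of -2.61 that was -1.40 with that covariate. Within the vehicle group Asns, Gpt2 and Psat1 were, like Met, highest in replicate 2 and lowest in replicates 3 and 6. Asns was at 152.7, 212.9, 50.6, 165.3 and 47.6 CPM in vehicle replicates 1, 2, 3, 4 and 6. In the nucleotide synthesis list 20 of 25 fell and 2 rose (adjusted p = 3.02e-05; adjusted p = 0.432 with an estimated correlation), or 21 and 2 adjusted over the list alone, and the folate enzymes Mthfd1 and Shmt1 fell, with log2 fold changes of -1.21 and -1.37, though Shmt1 did not pass with a surrogate variable (-0.86, adjusted p = 0.0722). With the index as a covariate 17 of the 20 amino acid response genes and 14 of the 20 nucleotide synthesis genes that fell still passed, and the list means were -0.96 against -1.83 and -0.50 against -0.66. The mean of the amino acid response list was -1.16 against vehicle replicates 3 and 6 only.

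Of 32 ribosome biogenesis genes, 29 fell and 0 rose (adjusted p = 5.35e-09; adjusted p = 0.552 with an estimated correlation), or 31 and 0 adjusted over the list alone. Dkc1, Nop16 and Nop10, nucleolar proteins, fell, with log2 fold changes of -1.23, -1.31 and -1.24. With the index as a covariate 13 of the 29 still passed, and the list mean was -0.37 against -0.73. Of 39 genes of oxidative phosphorylation, 25 fell and 0 rose (adjusted p = 2.04e-06; adjusted p = 0.68 with an estimated correlation), or 26 and 0 adjusted over the list alone, and with the index as a covariate 5 of the 25 still passed, at a list mean of -0.26 against -0.49. Cycs (cytochrome c) fell from 45.9 ± 6.65 to 17.9 ± 3.22 CPM, and Cyc1 and Ndufa4 had log2 fold changes of -1.12 and -0.84. Of 31 genes of the tricarboxylic acid cycle and acetyl-CoA supply, 14 fell and 4 rose (adjusted p = 0.0142; adjusted p = 0.68 with an estimated correlation), or 15 and 4 adjusted over the list alone. Me1 and Idh2, NADPH-producing enzymes, fell, with log2 fold changes of -4.91 and -3.12, and that of Dlat was -0.93. These were -2.83, -1.62 and -0.48 with the index as a covariate, where Cyc1 was at -0.49, and -3.25, -1.92 and -0.58 against vehicle replicates 3 and 6 only. Within the vehicle group Me1 and Idh2 were also highest in replicate 2 and lowest in replicates 3 and 6. Me1 was at 54.9, 88.2, 12.5, 58.8 and 16.6 CPM in vehicle replicates 1, 2, 3, 4 and 6. Acss1 and Acss2, which make acetyl-CoA from acetate, rose from 35.8 ± 15.4 to 67.4 ± 10.1 CPM and from 15.99 ± 2.12 to 25.5 ± 2.58 CPM, with adjusted p values of 0.0125 and 0.00133. The tricarboxylic acid list did not pass with the index as a covariate (adjusted p = 0.157), where the adjusted p of Acss1 was 0.735. With a surrogate variable that list did not pass (adjusted p = 0.71), nor did Acss1, whose log2 fold change went from 0.91 to 0.04 (adjusted p = 0.971), and Acss2, whose log2 fold change was no smaller, at 0.79 against 0.67 (adjusted p = 0.0887). The adjusted p of Cyc1, Ndufa4, Dlat, Idh2, Dkc1, Nop16 and Nop10 was then 0.412, 0.234, 0.263, 0.0549, 0.065, 0.099 and 0.113, at log2 fold changes of -0.29, -0.43, -0.32, -1.18, -0.56, -0.79 and -0.71.

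In the cell cycle list 20 of 36 members fell and 2 rose (adjusted p = 0.000197; adjusted p = 0.68 with an estimated correlation), or 21 and 2 adjusted over the list alone. With a surrogate variable the mean of the list was -0.03 (adjusted p = 0.843), and Ccne1, E2f1 and Mcm2 did not pass (log2 fold changes of -0.86, -0.60 and -0.94, adjusted p of 0.0696, 0.163 and 0.0601), against -1.31, -1.29 and -1.13. The members with the smallest p act in the G1 to S transition and in replication: Ccne1 fell from 33.1 ± 5.81 to 13.4 ± 2.47 CPM, E2f1 from 46.6 ± 10.2 to 19.1 ± 4.10 CPM and Mcm2 from 161 ± 12.5 to 73.6 ± 19.3 CPM. Mki67, a marker of cycling cells, rose from 497 ± 77.0 to 735 ± 136 CPM (log2 fold change 0.56 ± 0.14, adjusted p = 0.00708). Its log2 fold change was 0.45 against vehicle replicates 3 and 6 only (adjusted p = 0.0817). With a surrogate variable and with the index as a covariate it was 0.49 and 0.38 (adjusted p of 0.355 and 0.202). With that covariate 12 of the 20 genes that fell still passed, and the list mean was -0.24 against -0.54. Myc fell from 62.9 ± 15.2 to 18.5 ± 3.77 CPM, a log2 fold change of -1.77 ± 0.19 (adjusted p = 0.000214).

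T cell state genes did not move as one. In the memory and stem-like list 7 of 20 members rose and 3 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.276). Foxo1, Satb1 and Tcf7, transcription factors of naive and memory T cells, rose from 135.1 ± 60.3 to 409.8 ± 52.96 CPM, from 160.5 ± 70.0 to 439 ± 102 CPM and from 69.5 ± 15.8 to 140.8 ± 33.0 CPM, with log2 fold changes of 1.60 ± 0.26, 1.45 ± 0.27 and 1.02 ± 0.18. None of the 3 passed with a surrogate variable (log2 fold changes of 0.61, 0.43 and 0.73, adjusted p of 0.251, 0.52 and 0.238). Satb1 did not pass with the index as a covariate (0.66, adjusted p = 0.0559), where Foxo1 was at 0.81 (adjusted p = 0.0074). Tcf7 rose by 0.75 against vehicle replicates 3 and 6 only (adjusted p = 0.014), and did not pass with the index as a covariate (adjusted p = 0.0591) or with scaling to CD8 T identity genes (adjusted p = 0.127), which moved the median of all rows to -0.65. Il7r (log2 fold change 0.24 ± 0.26) and Eomes (0.36 ± 0.32) did not pass, with adjusted p values of 0.451 and 0.36, and Il7r was lower with that covariate (-0.59, adjusted p = 0.0248) but higher with limma-voom (0.42, adjusted p = 0.0432). In the exhaustion list 10 of 22 members rose and 1 fell (adjusted p = 0.0117; adjusted p = 0.785 with an estimated correlation), also adjusted over the list alone. The list did not pass without vehicle replicate 2 (adjusted p = 0.0569), and its mean turned from 0.49 to -0.08 with the index as a covariate. Of the members that rose, Nr4a1, Nr4a2 and Nr4a3 are orphan nuclear receptors also induced by T cell receptor signalling. Nr4a3 rose from 566 ± 190 to 1647 ± 239 CPM, Nr4a1 by 0.88 and Nfatc1 by 0.87 on the log2 scale. With a surrogate variable these 3 did not pass: Nr4a3 was at 0.74 against 1.54 (adjusted p = 0.104) and Nfatc1 at 0.22 (0.601), while Nr4a1 stayed about as large, at 0.77 (0.0977). Nr4a3 passed with the index as a covariate at 0.94. Nfatc1 did not pass with the index as a covariate (0.36, adjusted p = 0.0786), and with scaling to CD8 T identity genes, and its common shift, neither did Nr4a1 and Nfatc1 (adjusted p of 0.491 and 0.108). Pdcd1, which encodes PD-1, rose from 946 ± 322 to 1591 ± 248 CPM (adjusted p = 0.0154), and its adjusted p was 0.159 against vehicle replicates 3 and 6 only, where that of the list was 0.512. With the index as a covariate and with a surrogate variable Pdcd1 was at 0.10 and 0.01 against 0.75 (adjusted p of 0.765 and 0.989). Havcr2 was at 237 ± 85.5 and 244.9 ± 25.3 CPM (adjusted p = 0.867), and turned to -0.41 against vehicle replicates 3 and 6 only (adjusted p = 0.0249) and to -0.66 with the index as a covariate (adjusted p = 0.00224).

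In the effector list 5 of 23 members rose and 5 fell (adjusted p = 0.918), also adjusted over the list alone. The list was lower with the index as a covariate (mean -0.41, adjusted p = 0.03) and with a surrogate variable (-0.31, adjusted p = 0.0362). The chemokine gene Ccl3 and Zeb2, a factor of terminal effector cells, fell, with log2 fold changes of -1.52 and -1.03, and Fasl rose from 58.2 ± 14.3 to 116.6 ± 18.9 CPM. Gzmb, which encodes granzyme B, fell from 975 ± 205 to 638 ± 194 CPM (adjusted p = 0.0301), a call that ended without vehicle replicate 1 or 6 (adjusted p of 0.0652 and 0.0624) and without JHU083 replicate 2, 5 or 6 (0.0709, 0.0769 and 0.0671). Ifng was at 311 ± 107 and 333 ± 70.9 CPM (adjusted p = 0.749). It was lower with the index as a covariate (-0.61, adjusted p = 0.0453) and with scaling to CD8 T identity genes (-0.46, adjusted p = 0.0341), where the median of all rows was -0.65, and did not pass against vehicle replicates 3 and 6 only (-0.31, adjusted p = 0.221). Of 21 activation and costimulation genes 8 rose and 7 fell (adjusted p = 0.949), or 9 and 7 adjusted over the list alone. Jun and the costimulatory receptor Tnfrsf4 fell, with log2 fold changes of -1.11 and -1.19. Of 29 interferon response genes 6 rose and 5 fell (adjusted p = 0.594), or 5 and 5 adjusted over the list alone. Mx1 and Trim30a rose by 1.19 and 0.92 and Gbp2 fell by 2.07 on the log2 scale. Against vehicle replicates 3 and 6 only, the mean of that list was 0.27 and it was higher in JHU083 (adjusted p = 0.0198), as it was with the index as a covariate (adjusted p = 0.000108). Of 24 p53 and apoptosis genes 8 rose and 9 fell (adjusted p = 0.978), or 8 and 10 adjusted over the list alone. Bcl2l11, which encodes the pro-apoptotic protein BIM, rose from 165 ± 57.8 to 470.5 ± 31.4 CPM, and Plk2 and Eda2r fell, with log2 fold changes of -1.75 and -3.23. With a surrogate variable Zeb2, Fasl, Jun, Mx1, Trim30a, Gbp2, Bcl2l11, Plk2 and Eda2r did not pass, with adjusted p values from 0.0675 to 0.372 and log2 fold changes of -0.65, 0.44, -0.38, 0.65, 0.42, -0.74, 0.79, -0.90 and -1.12. Gzmb did not pass there either (adjusted p = 0.287), at a log2 fold change no smaller, -0.77 against -0.61. The log2 fold changes of Gbp2, Eda2r and Bcl2l11 with the index as a covariate were -0.88, -1.64 and 0.92. In these last 2 lists and in the activation list the mean log2 fold change was negative (-0.10, -0.23 and -0.17) while camera's direction was up, and their medians were 0.13, 0.14 and -0.05. The effector list had a median of 0.01 and a mean of -0.04.

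**Figure D3:**
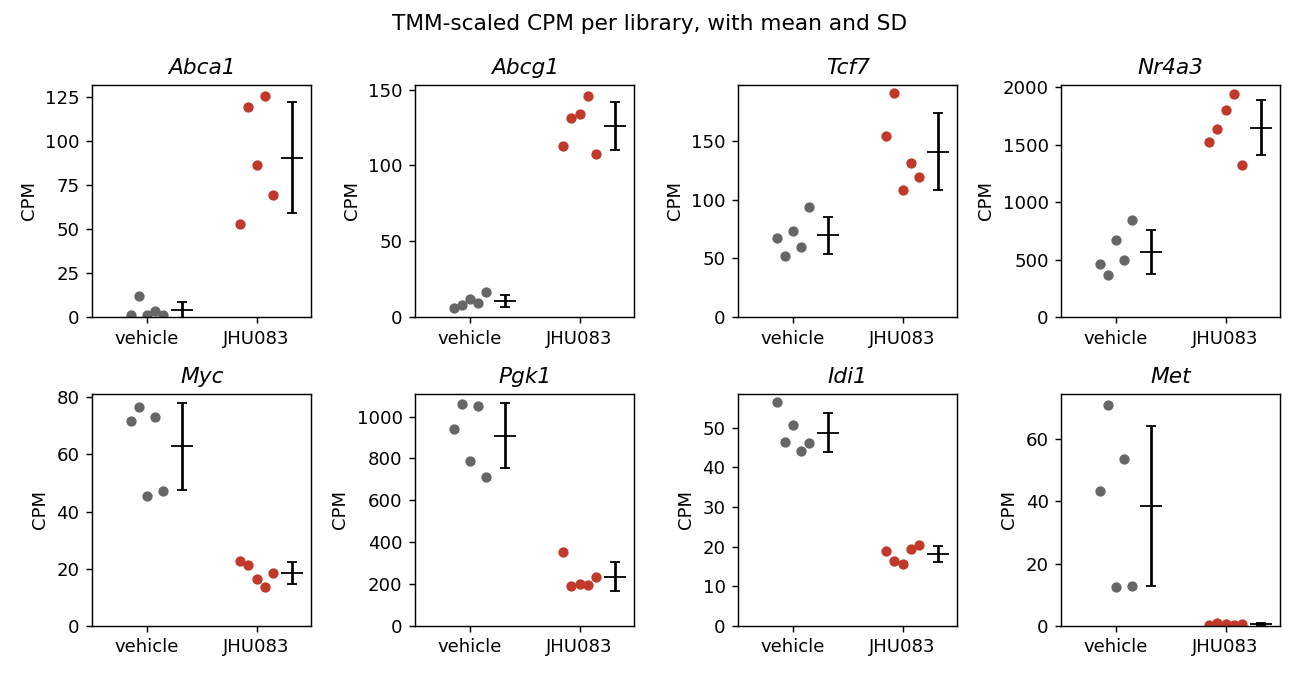
TMM-scaled CPM of 8 named genes, with 1 point per library, and the group mean with its SD as a bar beside the points. Abca1, Abcg1, Tcf7 and Nr4a3 were higher and Myc, Pgk1, Idi1 and Met lower in every JHU083 library than in every vehicle library.

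Among the remaining genes named by rule, Capg (271 ± 41.5 and 230 ± 32.1 CPM), Klre1 (68.9 ± 20.5 and 98.7 ± 25.3 CPM) and Ighm (19.1 ± 3.56 and 15.3 ± 8.81 CPM) did not pass, with adjusted p values of 0.15, 0.0715 and 0.447. Ctsb, Mmp9 and Anxa3 fell, with log2 fold changes of -0.35, -2.96 and -4.20, and the Ctsb call ended without vehicle replicate 4 (adjusted p = 0.0547) and without JHU083 replicate 2 or 5 (0.057 and 0.0592). With a surrogate variable Ctsb and Mmp9 did not pass (log2 fold changes of -0.13 and -0.80, adjusted p of 0.814 and 0.355). The index as a covariate left Mmp9 at -1.18 and Anxa3 at -2.18, and the Ctsb call ended (-0.10, adjusted p = 0.677). With limma-voom Capg and Klre1 passed (adjusted p of 0.0352 and 0.00469). Without vehicle replicate 2 Capg passed (adjusted p = 0.0253), and so did Klre1 without vehicle replicate 3 or 6 (0.0343 and 0.0451). The authors' deposited table lists 4355 significant rows, 1448 higher and 2907 lower in JHU083, fewer than the 3671 and 4192 called here. Of the authors' rows, 4222 were tested here, 4032 were called in the same direction and 2 in the opposite direction. Tcf7, Acss2, Ctsb and Alas2, called here, were not significant there (q of 0.148, 0.149, 0.127 and 0.449). Klre1, not called here, was significant there (q = 0.0218).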

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

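Of the tests below, those of macrophages as the only source, of carried-over RNA as the whole cause and of withheld estimates were chosen after their results had been seen. In 12 of 176 groups of 5 libraries 1 library lay far from the others, by a gap of more than 0.71 of the range, where chance gives about 8.8.

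In vehicle replicate 2, Abca1 was at 11.8 CPM against 0.911 to 3.38 in the other vehicle libraries, and Cd74 at 299 CPM against 53.9 to 78.4. The macrophage markers summed to 1600 CPM there, against 493 to 789, and the dendritic cell markers to 676 CPM against 119 to 177. In JHU083 replicate 1, Psat1 was at 55.5 CPM against 42.1 to 44.9 in the other JHU083 libraries, Mthfd1 at 40.0 against 27.1 to 29.7, Pgk1 at 352 against 187 to 232, Eno1 at 651 against 357 to 423 and Pfkl at 89.0 against 49.0 to 59.6. The erythroid markers summed to 5.91 CPM in that library, against 0.477 to 0.989. In JHU083 replicate 6, Qrfp was at 39.8 CPM against 23.0 to 26.9. In JHU083 replicate 2 the neutrophil markers summed to 25.9 CPM against 12.9 to 16.2.

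Genes of adherent cells were lower in JHU083. RNA of tumour or stromal cells carried over into the vehicle sorts is a candidate source, although the gate required CD45: in the 3 vehicle libraries with the highest index the median ratio of 27 other pan-leukocyte genes to their JHU083 mean was 0.549, where such RNA lowers the share of leukocyte transcripts. Macrophages that express C1qa, C1qb, C1qc and Lyz2 are argued against as the only source, since these 4 genes summed in vehicle replicate 4 to 0.0927 of the level in replicate 2 while the index was at 0.693 of it, and to 2.61 CPM in vehicle replicate 1 against 3.28 CPM in JHU083 replicate 4. The longer macrophage list excludes nothing: it summed to 789 and 1600 CPM in vehicle replicates 4 and 2, but also to 393 ± 36.3 CPM in JHU083. An effect of treatment on the share of tumour cells in the tissue, and so on what was carried over, stays open and was not tested.

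Genes of glycolysis, hypoxia, sterol and lipid synthesis and ribosome biogenesis were also lower, though with an estimated correlation these lists did not pass (adjusted p of 0.365, 0.367, 0.365 and 0.552). Carried-over RNA in proportion to the adherent-cell index was tested as the whole cause, with the index in a model of the list mean per library. The log2 differences were then -1.01 ± 0.14, -0.86 ± 0.17, -0.93 ± 0.06 and -0.38 ± 0.06 (SE, 7 error degrees of freedom), against -1.19, -1.36, -1.41 and -0.71 without it. With the index as a covariate in the gene test, 18 of 20 glycolysis genes, 12 of 18 hypoxia genes and 16 of 20 sterol and lipid genes that fell still passed in the same direction. For ribosome biogenesis 13 of 29 did. These fits cannot decide whether carried-over RNA was the whole cause. Met, which followed the index within the vehicle group, also still passed with it, at -4.18 (adjusted p = 2.43e-06), as did Hmga2 at -4.2. The fibroblast and endothelial list did not (camera adjusted p = 0.199). Every JHU083 library had a lower index than every vehicle library, so carried-over RNA and a change in the T cells cannot be told apart. The index need not track every source of carried-over RNA: Col1a1 was at 51.6 CPM in JHU083 replicate 5 and 5.98 CPM in vehicle replicate 3. Other sources or a share of the change stay open, as does an effect of JHU083 on the T cells.

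Abundant genes at 0 in a whole group may be estimates withheld by the quantifier, since 4 of 4 such called loci carry the mark for too many fragments in the authors' deposited table. These are Hspa1a, Hspa1b, Gm20481 and mt-Nd1,mt-Nd2. Whether any of them differed between the groups is not measured by these files.

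Other splits of the 10 libraries were counted over 100 splits into 5 and 5. Only 1 split, the real one, gave as many genes higher (3671) or lower (4192) in JHU083, and the highest of the others was 0 for both. Every other split mixes the groups and puts their difference into the spread within a group, which lowers its counts. The splits therefore say little about the size of the real counts. For the fixed lists 97 splits gave at least 2 lists in 1 direction and 19 gave at least 11, the real split with its 2 higher and 11 lower lists included. The highest of the others was 13, and a split with that count kept 4 vehicle libraries on 1 side. Such splits carry part of the group difference, so their counts do not measure chance alone. The splits therefore cannot decide whether the list counts arose by chance, which is not excluded.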

How the results depend on the processing

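The index as a covariate, vehicle replicates 3 and 6 only, scaling to CD8 T identity genes and removal of HIDATA and FAIL loci were chosen after seeing the data. No gene called here was called in the opposite direction under any setting of the gene test. Genes higher and lower numbered 2900 to 5128 and 3278 to 5070 over the other scalings, filters, tests and the block, 2874 to 3984 and 3649 to 4460 with a library left out, and 3667 and 4190 without HIDATA and FAIL loci. They numbered 90 and 263 with the surrogate variable, 882 and 1527 with the index as a covariate, 1481 and 1964 against vehicle replicates 3 and 6 only, and 448 and 7243 with scaling to CD8 T identity genes. The cause was not tested. Deviations from the group means gave same-number correlations of 0.192, 0.214, -0.078 and 0.122. Different-number correlations ranged from -0.245 to 0.235, so the check neither shows nor excludes pairing by number. With the number as a block, which kept 8 libraries, 3374 genes were higher and 3848 lower. Ctsb, Alas2 and the dendritic cell list did not pass, and Klre1 did (adjusted p = 0.0365). The same 8 libraries without a block gave 3446 and 4043. There Ctsb (0.0534), the dendritic cell list (0.057) and Gzmb (0.0978) did not pass, and Klre1 did (0.0463).

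Fixed lists higher numbered 1 with the surrogate variable, 1 with fry, 1 with the covariate, 0 with an estimated correlation and 1 to 2 with a library left out, the 1 being without vehicle replicate 2. Fixed lists lower numbered 0 with an estimated correlation and 9 to 13 under the other settings. The number of marker lists with a different summed CPM was 0 to 8 with a library left out. It was 0 without JHU083 replicate 2, 4 or 6 and 2 without JHU083 replicate 5, with the lost calls at adjusted p values of 0.0567 to 0.0617. In these fits the fibroblast and endothelial difference ranged from -5994 to -6289 CPM, against -6129 with all libraries. The cause was not tested.

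These values changed sign; the cause was not tested. With total-count scaling Havcr2 was -0.01 and without a filter the NK and gamma-delta list was 0.18. With the block the effector, CD4 and regulatory T and NK lists were 0.05, 0.04 and 0.09, and with the same 8 libraries and no block the first 2 were 0.03 and 0.02. With the surrogate variable Il7r, Eomes, Ifng, Havcr2, Cd8a and Klre1 were -0.60, -0.39, -0.73, -0.81, -0.21 and -0.08, and the memory, exhaustion, interferon, CD8 T identity, NK, macrophage and neutrophil lists -0.08, -0.19, 0.36, -0.05, 1.02, 1.05 and 0.12. With the covariate Il7r, Eomes, Ifng, Havcr2, Cd8a and Klre1 were -0.59, -0.54, -0.61, -0.66, -0.10 and -0.05, and those 7 lists -0.16, -0.08, 0.47, 0, 0.92, 0.84 and 0.11. Against vehicle replicates 3 and 6 only Il7r, Eomes, Ifng and Havcr2 were -0.25, -0.14, -0.31 and -0.41, and the memory, interferon, NK and tumour epithelial lists -0.02, 0.27, 0.87 and 0.26. With scaling to CD8 T identity genes, which moved the median of all genes from 0.04 to -0.65 and has Cd8a in its own list, Mki67, Il7r, Eomes, Ifng, Havcr2, Acss2, Cd8a and Klre1 were -0.08, -0.28, -0.15, -0.46, -0.52, -0.05, -0.08 and -0.08, and the memory, exhaustion and CD8 T identity lists -0.49, -0.10 and -0.07. On the mean of log2(CPM + 1) the CD4 and regulatory T and NK marker differences were -0.0354 and -0.0100. With a library left out Havcr2 ranged from -0.11 to 0.19 and Ifng from -0.08 to 0.24. The interferon list ranged from -0.24 to 0.03, the NK list from -0.43 to 0.30, the CD4 and regulatory T list from -0.18 to 0.04, the effector list from -0.15 to 0.05, and the summed CPM difference of the CD4 and regulatory T markers from -20.5 to 185.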

Other observations

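The lists below were written after the comparison had been seen and before the values of their members were looked at, so none is independent of the first results. They were not tested with the adherent-cell index as a covariate. Carried-over RNA in the vehicle libraries and a change in the T cells therefore cannot be told apart for them. Of 19 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 17 fell in JHU083 and 0 rose (camera adjusted p = 1.15e-06; adjusted p = 0.337 with an estimated correlation), and 11 fell against vehicle replicates 3 and 6 only. Lars fell from 171.6 ± 65.2 to 54.9 ± 3.91 CPM (SD, 5 libraries each). Of 25 proteasome subunit genes, 24 fell and 0 rose (adjusted p = 4.29e-07; adjusted p = 0.337 with an estimated correlation), and 11 fell against vehicle replicates 3 and 6 only. Psma5 fell from 119 ± 35.1 to 55.5 ± 7.02 CPM.

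Of 24 autophagy and lysosome genes, 14 rose and 3 fell (adjusted p = 0.00726; adjusted p = 0.337 with an estimated correlation), and 6 rose and 1 fell against vehicle replicates 3 and 6 only. Ulk1, a kinase that starts autophagy, rose from 51.3 ± 9.77 to 70.8 ± 5.17 CPM, but did not pass against vehicle replicates 3 and 6 only (adjusted p = 0.13). Of 25 genes of histone and DNA methylation, 17 rose and 2, Ezh2 and Dnmt1, fell (adjusted p = 0.000474; adjusted p = 0.337 with an estimated correlation). Against vehicle replicates 3 and 6 only 5 rose and 3 fell. Kdm6b, a histone demethylase, rose from 143.5 ± 38.3 to 363 ± 41.2 CPM. Of 20 trafficking receptor genes, 9 rose and 1, Ccr7, fell (adjusted p = 0.00973; adjusted p = 0.337 with an estimated correlation), and 5 rose and 2 fell against vehicle replicates 3 and 6 only. Cxcr3 rose from 15.2 ± 4.18 to 43.3 ± 5.45 CPM, and Ccr7 fell from 239.6 ± 100 to 84.3 ± 23.7 CPM. Itgae and Cxcr4 did not pass, with adjusted p values of 0.959 and 0.129. The median log2 fold changes of the autophagy, methylation and trafficking lists were 0.3, 0.42 and 0.54. That of the CD8 T identity list was 0.61, so on the median these lists rose no more than CD8 T identity genes did.

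Higher activity of the liver X receptors, which induce Abca1 and Abcg1, was a hypothesis for the rise of those genes, and its prediction was written before the other targets were looked at. Of 5 other targets, 2 rose, Smpdl3a by 0.92 and Arl4c by 0.63 on the log2 scale. Lpcat3 and Pltp fell, with log2 fold changes of -0.74 and -1.69, and Nr1h3 did not pass (adjusted p = 0.47). Against vehicle replicates 3 and 6 only 2 rose and 0 fell. The prediction was that at least 3 of the 5 would rise if the hypothesis held, and fewer than 2 if not. The 2 that rose fall short of the first and leave the hypothesis open. The adherent cells whose genes were high in vehicle may express Lpcat3 and Pltp, which was not tested.

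The authors' deposited enrichment sheet gives a memory against KLRG1-high CD8 T cell set an enrichment score of 0.405 and a normalized score of 1.23. For this enrichment it lists a nominal p of 0, a false discovery q-value of 0.16 and a family-wise p of 0.17. The sheet does not state which of its classes is JHU083, so no direction is given. In the comparison made here 117 of its 164 members were tested, 42 rose and 24 fell, and the set did not pass (unadjusted camera p = 0.0891, and 0.215 with an estimated correlation).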
